A study of Mus musculus with 1086 samples.

How the data were processed

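Liver mRNA libraries of Diversity Outbred (DO) mice and founder strain males were sequenced as 100 base single-end reads, per the labels. The labels list 1086 sequencing records of 414 animals, among them 286 DO animals, of which 277 were analysed and 9 were not analysed here. All 128 founder males were analysed. Every column of the 3 tables was matched to a label, and 0 were left over. DO animals of block 1 (92 animals, 2 to 3 runs each) and block 2 (185 animals, 4 runs each) held all 4 groups of sex and diet. Sex is the genotyped sex of the labels, which differs from the letter of the sample name in 2 animals. Each animal is 1 replicate.

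Per the submitters' processing notes, reads were processed with CASAVA 1.8.0, aligned with Bowtie 0.12.8 and quantified with RSEM 1.2.1 on NCBIM37 (mm9). The deposited tables hold a signal that the authors normalized per sample, and not read counts. In each column of the NCBIM37 and founder tables the upper quartile of the deposited signal was 1. In the individualized table it averaged 2.55 (2.40 to 2.89), and what the authors divided by there is not given in the sources used here. Low values of each column were spaced at 1 step, so counts could be recovered by dividing by that step. Within a tolerance of 0.1, 99.9% of recovered values below 20.5 were whole in both DO tables and 82.7% in the founders (80.5 to 84.6), whose values are therefore treated as estimated counts. The DO tables hold 17144 genes (individualized) and 17135 (NCBIM37), and that of the founders 24965. The files carry Ensembl identifiers, and symbols came from GENCODE M21, which held 16056, 16031 and 22760 of them. Because that annotation lies on another build than the files, no coordinates are given.

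The plan, the gene lists, the rule for naming genes and the first set of alternative settings were written before the data were examined. The plan set edgeR for expected counts and limma for a normalized unit. The values being normalized, the test was limma 3.58.1 with a trend on log2(x + 1), where x is the deposited value times 1 constant for each file (1067.99 individualized, 1442.93 NCBIM37, 114.929 founders), called count equivalents. Adding the pseudocount of 1 to count equivalents and not to the deposited signal, and centring each animal on its median gene in the alignment comparison, were decided after the scale of the values was seen. Genes with 10 or more count equivalents in at least as many samples as the smallest group were tested, and adjusted p values are Benjamini-Hochberg with a threshold of 0.05. The DO model held 4 groups and block, and the founder model 16 groups. Diet and sex effects are means over the other factor, and strain effects and the strain by diet interaction are F-tests. Changes are given with the SE of the model, means of a group with the SD over animals.

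Alignments were compared within each animal by limma treat with a null fold of 1.2. A sign-flip permutation test of their deposited totals was run and is not reported, since the tables are normalized differently. The spread there is between animals, since both tables hold the same reads. The 28 gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which asks whether a list moves without comparing it with other genes. Lists with a call, and some without, are described. Named genes exclude predicted symbols. For sex and each diet effect they are the 8 largest increases and 8 largest decreases among genes past the threshold with a mean log2 CPM of 1 or more. Under the same bound they are the 6 smallest p for interactions, the 12 widest ranges for strain and the 2 largest either way for each strain against the other 7, and without it the 8 largest gains and losses for alignment. For lists they are the 2 to 4 members with the smallest p. Not every gene that the rule picks is described. Xist and its Y-linked companions for sex, and Nnt, Hc, Glo1, H2-Ea and Mx1 for strain, were to be named whatever their values. H2-Ea and, in the DO, the Y-linked genes were not analysed here.

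Precision rests on 66 to 73 animals per DO group and 8 per founder group. On simulated data with 200 changed genes and a dispersion of 0.1, the test recovered 100% of 1.5-fold changes for DO sex and diet and 91% for their interaction. It recovered 99% for founder diet, 39% for strain, 8% for diet within 1 strain and 0% for a strain by diet difference in 1 strain, and at 2-fold 98%, 98%, 55% and 5% of these last 4. Unchanged genes made up at most 9.09% of calls. The dispersion was a fixed setting and was not estimated from these animals, so these shares do not apply to genes that varied more. In simulated lists, 10 of 10 changed and 0 of 10 unchanged lists were called. Genes were drawn independently there, so this cannot show how often lists of correlated genes are called falsely.

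Alternatives covered the test (edgeR 4.0.16, DESeq2 1.42.0 and limma-voom on recovered counts of the DO), scaling, filter, threshold, pseudocount, alignment, block, lane, and leaving out animals or strains. With edgeR on recovered counts 10598 genes passed for sex, 10074 for diet and 1788 for the interaction. For every comparison 100 regroupings of the samples, the real one included, were tested in the same way. Identity was checked by correlating columns: each of the 277 DO animals matched its own column best between the tables, and 126 of 128 founder males lay nearest to an animal of their labelled strain. Computation used R 4.3.3, the data.table package (1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.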

Results

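Liver messenger RNA was measured by sequencing in 277 Diversity Outbred (DO) mice and in 128 males of the 8 inbred strains from which the DO stock was bred. Each DO animal carries its own mosaic of the 8 founder genomes. The founders were 129S1/SvImJ, A/J, C57BL/6J, CAST/EiJ, NOD/ShiLtJ, NZO/HILtJ, PWK/PhJ and WSB/EiJ, written below as 129S1, AJ, B6, CAST, NOD, NZO, PWK and WSB. Per the labels, the DO mice ate standard chow (6% fat by weight) or a high fat diet (22% fat by weight) from weaning and were 26 weeks old. There were 73 females on chow, 70 females on high fat, 68 males on chow and 66 males on high fat. The founder groups held 8 males per strain and diet at 26 weeks, or 20 weeks for NZO. The labels describe the founder diets both as a control diet with 17% of kcal from fat against one with 45% of kcal from fat and 34% sucrose by weight, and by the DO diets, so which was fed is not settled here. DO livers and founder livers came from different sites and were stored differently, per the labels. Recovered count totals per animal, in mega counts (M), averaged 145.8 M in the table aligned to individualized genomes (63.9 to 361.5), 76.2 M in the NCBIM37 table of the same animals (34.3 to 184.2) and 8.55 M in the founders (5.86 to 14.1). Whether the individualized table counts a read more than 1 time is open, so its totals are not taken as numbers of reads. Recovered totals in the individualized table averaged 109.9 M in females and 184.1 M in males.

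The comparison of DO males with DO females asks how sex shapes the liver transcriptome in a genetically mixed population. Males had far more mRNA of steroid and fatty acid hydroxylases such as Cyp4a12a and Cyp2d9, of the steroid dehydrogenase Hsd3b5, and of the major urinary proteins, which bind pheromones. Females had far more mRNA of the sulfotransferases Sult2a1 and Sult2a2, the female-specific repressor Cux2 and the X-inactivation RNA Xist. Cyp4a12a (ENSMUSG00000066071) was 221-fold higher in males (log2 difference 7.79 ± 0.19 SE; limma adjusted p = 2.12e-118). Its group means were 16.04 ± 0.51 (SD, n = 68) in chow males and 8.22 ± 1.96 (SD, n = 73) in chow females, on the log2 scale of count equivalents. Cyp2d9 was 24.1-fold higher (4.59 ± 0.08; adjusted p = 3.03e-149) and Hsd3b5 64.1-fold higher (6.00 ± 0.24; adjusted p = 2.28e-69). Cyp4a12b was higher in males by 7.19 ± 0.22, and Susd4 and Serpina4-ps1 were 30.5-fold and 30.2-fold higher. Mup20 and Mup-ps19 were 70.2-fold and 69.2-fold higher, although Mup genes and pseudogenes share sequence, so which copy the reads came from is uncertain. Sult2a2 (ENSMUSG00000070811) was 385-fold lower in males (-8.59 ± 0.20; adjusted p = 2.71e-121) and Xist (ENSMUSG00000086503) 339-fold lower (-8.40 ± 0.11; adjusted p = 2.73e-181). Sult2a1, A1bg and Cux2 were 320-fold, 258-fold and 72.6-fold lower in males. Cyp3a41b (-6.98 ± 0.17) and Cyp3a41a (-6.87 ± 0.17) were lower too, again with the copy uncertain. Of 16738 genes tested, 10520 (62.9%) differed between the sexes, 5130 higher and 5390 lower in males, and 576 by more than 2-fold. The genes named here passed in each of the 2 blocks with the same direction. Across 16693 genes the sex differences of the blocks had Pearson r 0.901 and Spearman rho 0.752, genes not being independent replicates. The blocks called 8051 and 9582 genes, with 5854 called by both in the same direction, 96 in opposite directions and 2298 expected by chance. With NCBIM37 alignment 10487 genes passed, 4290 higher and 6197 lower in males. Sizes depended on the model. DESeq2 on recovered counts gave smaller log2 differences for Cyp4a12a (6.43), Cyp4a12b (5.36), Sult2a2 (-6.66), Sult2a1 (-5.82, by limma -8.32), Cyp3a41b (-6.00), Cyp3a41a (-5.89) and Cux2 (-5.35), and larger ones for A1bg (-8.47, by limma -8.01), Mup20 (6.64) and Mup-ps19 (6.64). The reason was not tested.

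**Figure D1:**
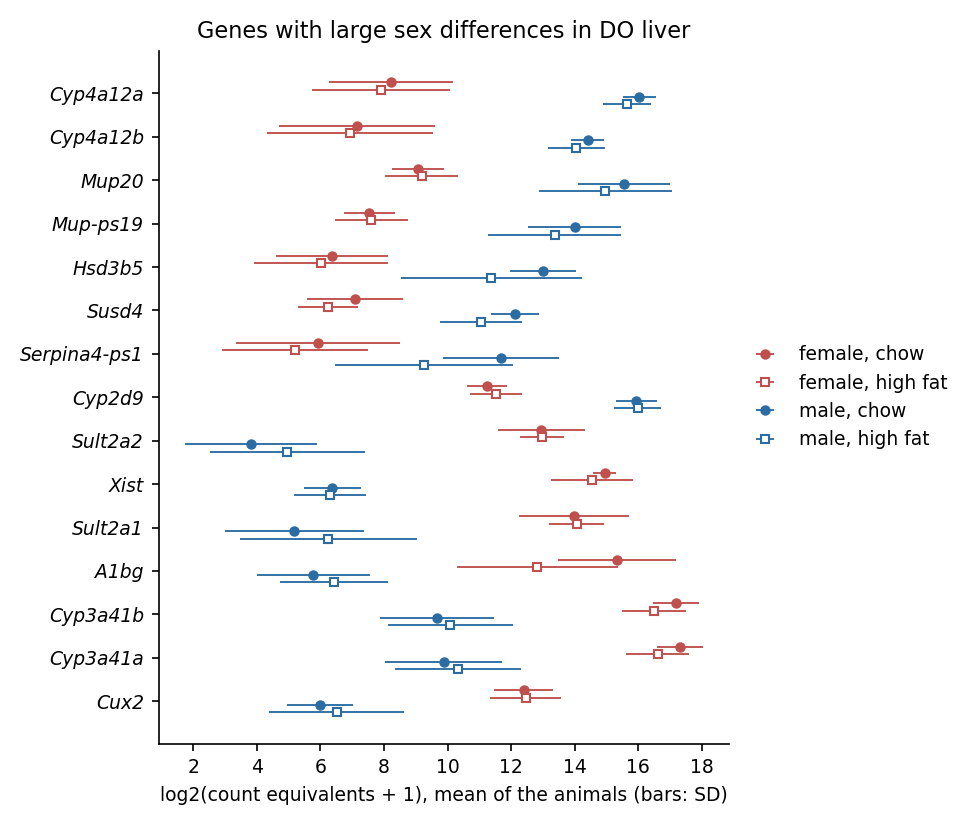
Mean and SD of log2(count equivalents + 1) of 15 genes in DO females (red) and males (blue) on chow (filled circles) and on high fat (open squares), with 66 to 73 animals per group. For Cyp4a12a the chow males stood at 16.04 and the chow females at 8.22.

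Gene lists fixed in advance separated the sexes along known liver programs. All 20 male-biased liver genes were higher in males (camera adjusted p = 6.5e-51; 20 adjusted over the list alone), and 21 of 22 female-biased genes were lower (adjusted p = 1.53e-51; 21 adjusted over the list alone), led by Prom1 (-4.85 ± 0.11 SE). The 4 X-linked genes with partners on the Y chromosome, which escape X inactivation, were all lower in males (adjusted p = 4.8e-05; 4 adjusted over the list alone), with Eif2s3x at -0.54 ± 0.02, Kdm6a at -0.51 ± 0.04 and Kdm5c at -0.23 ± 0.03. These 3 calls held with an estimated correlation. So did that of Xist (adjusted p = 1.16e-07), the 1 gene of its list tested in the DO, which leaves no correlation to estimate. Fatty acid and triglyceride synthesis was lower in males in 16 of 18 genes (16 adjusted over the list alone; adjusted p = 1.56e-06, but adjusted p = 0.246 with an estimated correlation), with the lipid remodelling enzyme Pnpla3 at -3.19 ± 0.20 and the desaturase Fads1 at -0.83 ± 0.05. Fatty acid oxidation was lower in 16 of 24 (16 adjusted over the list alone; adjusted p = 3.57e-05, adjusted p = 0.261 with an estimated correlation), led by Cyp4a10 (-1.99 ± 0.14) and Vnn1 (-2.19 ± 0.16). Cholesterol synthesis and uptake was lower in 21 of 23 (22 adjusted over the list alone; adjusted p = 6.12e-05, adjusted p = 0.424 with an estimated correlation), with Pmvk at -0.75 ± 0.09 and the squalene epoxidase Sqle at -1.11 ± 0.16. The unfolded protein response was higher in males in 11 of 13 genes (12 adjusted over the list alone; adjusted p = 0.000102, adjusted p = 0.0788 with an estimated correlation), including Xbp1 (0.56 ± 0.04), Sdf2l1 (1.12 ± 0.10) and the chaperone Hspa5 (0.64 ± 0.06). Markers of immune cells were lower in males: 14 of 15 macrophage genes (15 adjusted over the list alone; adjusted p = 0.000663, adjusted p = 0.287 with an estimated correlation), with Vsig4 at -0.71 ± 0.09 and Cd68 at -0.51 ± 0.07. Of 12 T, B and NK cell genes, 10 were lower and 1 higher (11 adjusted over the list alone; adjusted p = 0.00106, adjusted p = 0.246 with an estimated correlation), with Cd3g at -1.29 ± 0.12. The interferon, endothelial and cell division lists were also called lower in males (adjusted p = 0.0105, 0.023 and 0.0487), and none of these held (adjusted p = 0.519, 0.332 and 0.519 with an estimated correlation). Their lowest members included Gbp3 (-1.31 ± 0.11) and the proliferation marker Mki67 (-1.15 ± 0.12).

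The comparison of high fat with chow asks how the DO liver responds to dietary fat. With high fat the liver made more mRNA for storing fat and for burning fatty acids. It also made more for fatty acid synthesis and less for making cholesterol, but the calls of these 2 lists were lost with an estimated correlation (adjusted p = 0.111 each). The lipase and acyltransferase Pnpla3 (ENSMUSG00000041653) rose 7.94-fold (log2 change 2.99 ± 0.20 SE; limma adjusted p = 1.62e-33), the stearoyl-CoA desaturase Scd1 4.13-fold (2.05 ± 0.15; adjusted p = 1.15e-29) and the lipoprotein component Apoa4 4.94-fold (2.31 ± 0.13; adjusted p = 4.93e-46). The neurotrophin receptor Ntrk2, the pantetheinase Vnn1, the fatty acid hydroxylase Cyp4a14, the signalling regulator Rgs16 and the desaturase Scd2 rose 4.67-fold, 4.56-fold, 4.22-fold, 4.03-fold and 3.90-fold. Enho, which encodes the secreted peptide adropin, was 4.70-fold lower (-2.23 ± 0.18; adjusted p = 3.98e-27). The cholesterol synthesis enzymes Sqle, Idi1, Msmo1 and Cyp51 fell 4.44-fold, 3.72-fold, 3.14-fold and 2.96-fold. For Sqle (ENSMUSG00000022351) the log2 change was -2.15 ± 0.16 (adjusted p = 1.49e-29) and for Idi1 -1.90 ± 0.11 (adjusted p = 9.76e-45). The kinase subunit Camk2b fell 4.54-fold (adjusted p = 6.28e-06), Sult5a1 3.88-fold and Serpina4-ps1 3.00-fold. Changes in 5 of these genes were more than 1.5 times smaller as folds with DESeq2 on recovered counts: the log2 change was 1.51 for Ntrk2, 1.38 for Rgs16, -1.41 for Sqle, -1.27 for Camk2b (limma -2.18) and -1.27 for Sult5a1. Across the genome, 9867 of 16738 genes (58.9%) changed with diet, 5060 up and 4807 down, 260 of them by more than 2-fold. The 16 named genes passed in both blocks with the same direction. Among them the size differed most for Serpina4-ps1, with a log2 change of -2.67 in block 1 and -1.02 in block 2. Diet effects of the blocks had Pearson r 0.610 and Spearman rho 0.539 across genes, with 4454 genes called by both in the same direction (2055 expected by chance) and 421 in opposite directions.

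Among the gene lists, 10 were called for diet and 2 of those, for burning and storing fat, held with an estimated correlation. Fatty acid oxidation rose in 23 of 24 genes (23 adjusted over the list alone; camera adjusted p = 1.36e-13, adjusted p = 0.0465 with an estimated correlation), including the fasting hormone Fgf21 (2.31 ± 0.16 SE), Acaa1b (0.71 ± 0.06) and the carnitine transferase Cpt1a (0.59 ± 0.05). Lipid droplet genes rose in 12 of 13 (13 adjusted over the list alone; adjusted p = 5.21e-09, adjusted p = 0.0197 with an estimated correlation), with the acyltransferase Mogat1 at 3.02 ± 0.20, the droplet protein Cidec at 2.47 ± 0.17 and the fatty acid transporter Cd36 at 1.22 ± 0.10. All 23 cholesterol genes fell (23 adjusted over the list alone; adjusted p = 4.9e-15, adjusted p = 0.111 with an estimated correlation), with Mvk at -0.94 ± 0.06. Fatty acid synthesis rose in 16 of 18 genes and fell in 1 (17 adjusted over the list alone; adjusted p = 2.01e-11, adjusted p = 0.111 with an estimated correlation), with Fads2 at 1.11 ± 0.06 and Elovl5 at 0.97 ± 0.07. Glucose metabolism rose in 8 of 13 genes and fell in 2 (10 adjusted over the list alone; adjusted p = 0.00257, adjusted p = 0.111 with an estimated correlation), including the fructose kinase Khk (0.62 ± 0.06). Of the 20 male-biased genes 13 fell (13 adjusted over the list alone; adjusted p = 2.75e-05, adjusted p = 0.171 with an estimated correlation), with the oxysterol hydroxylase Cyp7b1 at -1.03 ± 0.12. Macrophage markers rose in 12 of 15 genes (12 adjusted over the list alone; adjusted p = 4.33e-05, adjusted p = 0.179 with an estimated correlation), led by Lgals3 (0.96 ± 0.09) and by Gpnmb (2.31 ± 0.25) and Trem2 (1.99 ± 0.23), which mark lipid-laden macrophages. All 7 cell division genes rose (7 adjusted over the list alone; adjusted p = 0.0018, adjusted p = 0.309 with an estimated correlation), with Birc5 at 0.70 ± 0.10 and Ccnb1 at 1.39 ± 0.23. Interferon genes rose in 12 of 14 (13 adjusted over the list alone; adjusted p = 0.00355, adjusted p = 0.461 with an estimated correlation), with Cxcl10 at 0.80 ± 0.11. The 4 X-linked genes with Y partners fell (4 adjusted over the list alone; adjusted p = 0.0137, adjusted p = 0.179 with an estimated correlation). Clock genes moved both ways without a call for the list (adjusted p = 0.612): Dbp rose by 1.29 ± 0.21 and Arntl fell by 1.27 ± 0.17. Hba-a1, a red cell gene, rose 2.46-fold, in a list of blood genes that was not called (adjusted p = 0.0866).

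**Figure D2:**
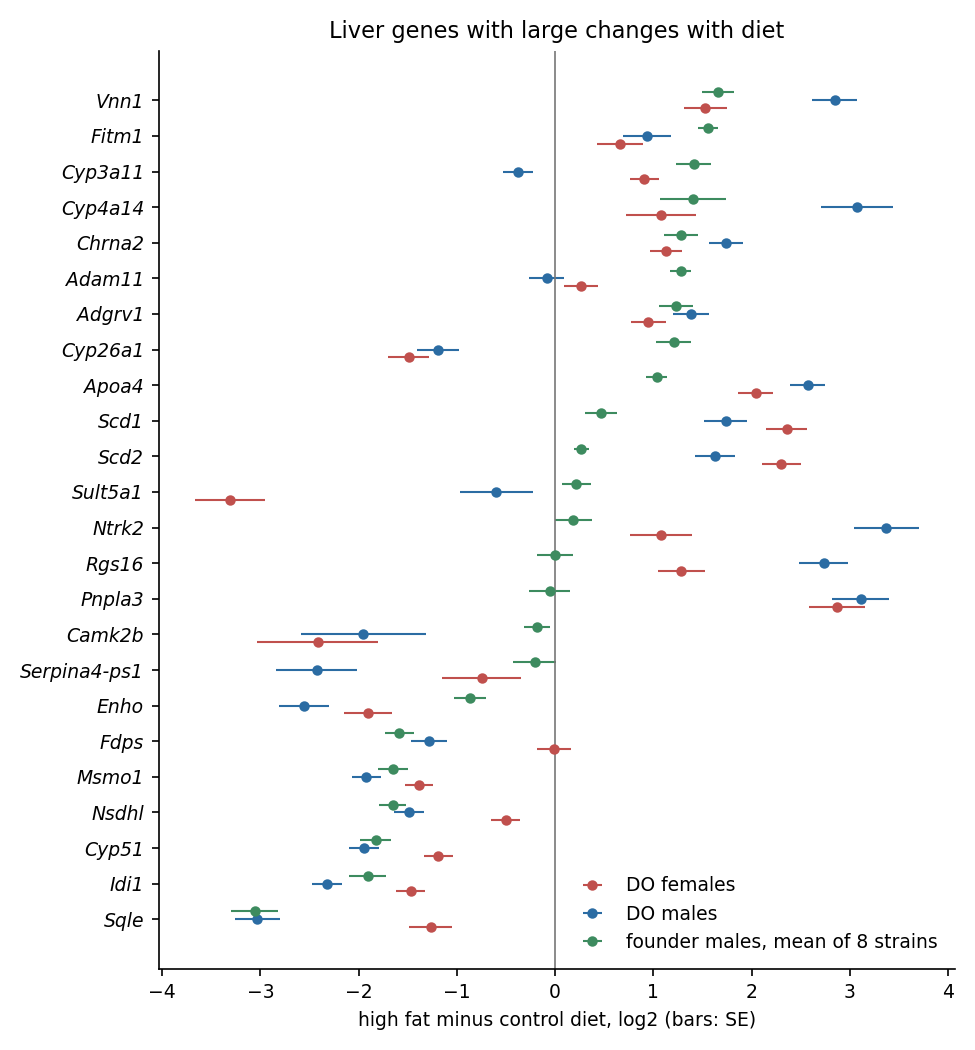
High fat minus control, log2 with SE bars, for 24 genes in DO females (red), DO males (blue) and founder males as the mean of 8 strains (green). Sqle fell in each of the 3, and Cyp26a1 rose in the founders by 1.21 and fell in the DO.

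The interaction of sex and diet asks which responses differ between males and females. Among the genes with the smallest p were the fatty acid binding protein gene Fabp5, the glutathione transferase genes Gstp1 and Gstp2, and Rtn4. Fabp5 (ENSMUSG00000027533) rose with high fat in females by 2.33 ± 0.19 SE, from 10.27 ± 0.91 (SD, n = 73) to 12.60 ± 1.32 (SD, n = 70). In males its change of 0.19 ± 0.20 did not pass (adjusted p = 0.456), and the difference was -2.14 ± 0.28 (adjusted p = 8.28e-10). Rtn4 (ENSMUSG00000020458), which shapes the endoplasmic reticulum, rose by 0.95 ± 0.08 in males and did not pass in females (0.09 ± 0.08, adjusted p = 0.326; difference 0.86 ± 0.11, adjusted p = 8.28e-10). Ttc39c fell in males (-0.71) and rose in females (0.23), a difference of -0.95 ± 0.12. The polyubiquitin gene Ubb moved the other way, up in males (0.34) and down in females (-0.13), a difference of 0.47 ± 0.06. The glutathione transferases Gstp1 and Gstp2 fell in males (-1.16 each) and not in females (0.17 and 0.16, adjusted p = 0.263 and 0.281), although reads cannot be told apart well between these paralogs. Ubb lost its call when the difference had to exceed 1.2-fold (adjusted p = 0.0673), the highest over its alternatives, the lowest being 2.10e-11. In all 1490 genes (8.90%) responded differently, 783 with a higher and 707 with a lower change in males. This set depended on the block: 2850 genes passed in block 1 and 771 in block 2, with 21.9% of the latter called in the same direction in block 1 (8.32% expected by chance), 13.1% called in the opposite direction, Pearson r 0.201 and Spearman rho 0.0467. Of the calls in block 2, 39.2% were higher in males, against 52.6% in all animals. The 6 genes named here passed in both blocks with the same direction.

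Female-biased liver genes were the 1 list whose interaction held with an estimated correlation (camera adjusted p = 1.92e-13, adjusted p = 0.0110 with an estimated correlation). In 12 of its 22 genes the change with high fat was higher in males (14 adjusted over the list alone). Cyp2b9 rose in males by 2.99 ± 0.36 SE (females -0.38 ± 0.35, adjusted p = 0.402), Hao2 rose in males by 2.10 ± 0.27, and A1bg fell in females (-2.42 ± 0.28) without passing in males (0.53 ± 0.29, adjusted p = 0.118). Cholesterol genes fell further in males, with 12 of 23 passing (18 adjusted over the list alone; adjusted p = 5.05e-13, adjusted p = 0.285 with an estimated correlation). Sqle fell by 3.03 ± 0.23 in males and by 1.27 ± 0.22 in females, and Fdps fell in males (-1.28 ± 0.18) but not in females (-0.01 ± 0.18, adjusted p = 0.963). In fatty acid oxidation the change with high fat was higher in males in 8 of 24 genes and lower in 1 (10 adjusted over the list alone; adjusted p = 2.77e-05, adjusted p = 0.335 with an estimated correlation), with a difference of 1.43 ± 0.29 for Cyp4a10. The fatty acid synthesis enzyme Acss2 had a lower change in males (difference -1.11 ± 0.21), in a list called at adjusted p = 0.00026 (adjusted p = 0.475 with an estimated correlation) with 4 of 18 genes passing (7 adjusted over the list alone). Among male-biased genes 5 of 20 had a lower change in males and 1 a higher one (7 adjusted over the list alone; adjusted p = 0.00102, adjusted p = 0.335 with an estimated correlation), with Selenbp2 at -1.36 ± 0.26. Another 7 lists, among them acute phase (adjusted p = 0.000248, adjusted p = 0.335 with an estimated correlation) and glucose metabolism (adjusted p = 0.00421, adjusted p = 0.285 with an estimated correlation), were called with 4 or fewer genes passing, and none held. Igfbp1, an insulin-repressed gene of the latter, rose in males by 1.28 ± 0.24 and not in females (-0.38 ± 0.23, adjusted p = 0.178). Taken by sex, 7236 genes changed in females (3689 up, 3547 down) and 8009 in males (4130 up, 3879 down). Of these, 4714 moved the same way in both sexes, against 910 up and 822 down expected by chance, and 110 moved in opposite ways, with Pearson r 0.689 and Spearman rho 0.683 across genes. Between the blocks the effects had Pearson r 0.557 in females and 0.514 in males. Block 1 alone called 4890 genes in females and 8671 in males, and block 2 alone 6056 and 3984. Which sex had more changed genes thus depended on the block. In males 22 of 23 cholesterol genes fell (adjusted p = 8.09e-22, adjusted p = 0.0333 with an estimated correlation) and 24 of 24 oxidation genes rose (adjusted p = 1.87e-16, adjusted p = 0.0331 with an estimated correlation). In females 17 of 18 fatty acid synthesis genes rose (adjusted p = 5.12e-16, adjusted p = 0.045 with an estimated correlation), as did 12 of 13 lipid droplet genes (adjusted p = 1.26e-08, adjusted p = 0.0209 with an estimated correlation).

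The comparison of founder strains asks how far liver expression differs among inbred genomes. Among genes with an assigned symbol and a mean log2 CPM of 1 or more, the 12 widest gaps between strain means included 5 Mup genes, the estrogen sulfotransferase Sult1e1, the glucuronosyltransferase Ugt1a10 and the steroid hydroxylase Cyp2a4. Moxd1 (ENSMUSG00000020000), a monooxygenase-like gene, spanned 10.8 log2 units, from 12.70 ± 0.37 in CAST to 1.86 ± 0.70 in AJ (SD, n = 16 per strain; limma adjusted p = 6.69e-49). Ugt1a10 spanned 9.76 units (CAST 10.52 ± 0.45, PWK 0.76 ± 0.90), Sult1e1 9.47 (WSB 9.75 ± 0.68, PWK 0.28 ± 0.52), and Cyp2a4 8.77 (PWK 10.37 ± 0.67, NOD 1.60 ± 0.74). The secreted trefoil peptide Tff3 spanned 8.88 units, highest in PWK (9.44 ± 0.78) and lowest in 129S1 (0.56 ± 0.76). The Mup genes have copies that share reads and are uncertain one by one: Mup13 (11.2 units), Mup18 (10.9), Mup2 (10.3), Mup20 (from 15.68 in PWK to 6.68 in CAST) and Mup19 (8.98). The pseudogenes Rps2-ps13 (10.5 units) and Ftl1-ps1 (8.55) carry the same doubt. Genes with known null or copy number alleles also differed: the mitochondrial transhydrogenase Nnt was lowest in B6 (8.72 ± 0.37; AJ 10.16 ± 0.21), and complement Hc was lowest in AJ (11.32 ± 0.31) and NOD (11.49 ± 0.57), against 13.84 ± 0.21 in WSB. Glo1 was highest in AJ (12.53 ± 0.13) and 129S1 (12.03 ± 0.22), and the antiviral Mx1 in NZO (6.71 ± 0.63) and PWK (6.05 ± 0.78). The class II gene H2-Eb1, which is on the antigen presentation list and not on this one, was lowest in WSB (1.01 ± 1.04) and PWK (2.91 ± 0.68). In all 12886 of 13535 genes (95.2%) differed among strains. Founder values came from a single alignment, so how far strain differences depend on alignment was not tested. The library labelled B6 control diet replicate 4 lay nearest to a NOD animal and the library labelled NOD high fat replicate 3 nearest to a B6 animal. Both were kept in their labelled groups, and without them 12973 genes differed.

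**Figure D3:**
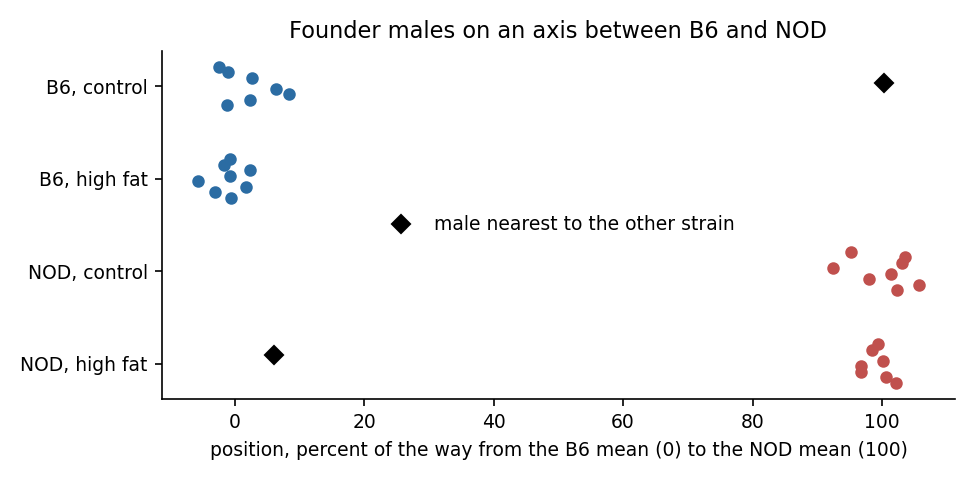
Position of each B6 and NOD male, as a percent of the way from the B6 mean (0) to the NOD mean (100), over 150 genes that separate these strains, in 4 groups of 8. Black diamonds mark the library labelled B6 control diet replicate 4, at 100.3, and the library labelled NOD high fat replicate 3, at 6.02.

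Each strain against the other 7 asks what marks that strain's liver. CAST stood apart in the most genes, and its interferon response was lower in all 14 genes of the list (camera adjusted p = 7.89e-06, adjusted p = 0.723 with an estimated correlation), with the regulator Irf7 at -2.85 ± 0.15 SE and Ifi44 at -3.79 ± 0.20. NZO was higher in all 14 (adjusted p = 4.75e-08, adjusted p = 0.272 with an estimated correlation), with Irf7 at 1.36 ± 0.15, and had 10 of 13 antigen presentation genes higher and 1 lower (adjusted p = 2.45e-05, adjusted p = 0.272 with an estimated correlation), including H2-Q10 at 1.56 ± 0.08. The contrasts in this paragraph include the pair of males nearest to another strain. Without that pair, B6 was also higher in all 14 interferon genes (camera adjusted p = 5.86e-05). NOD was then lower in 12 of them (camera adjusted p = 0.0231). Both values are at the preset correlation, and none with an estimated correlation is given for them. B6 had more mRNA of 11 of 14 lipid droplet genes (adjusted p = 1.15e-08, adjusted p = 0.011 with an estimated correlation), led by Fitm1 (2.51 ± 0.16) and the adipogenic regulator Pparg (2.65 ± 0.18). Also higher in B6 was Cfd, the 1 adipocyte gene tested (3.24 ± 0.23, camera adjusted p = 0.00407, adjusted p = 0.0211 with an estimated correlation). A single gene has no correlation to estimate, so Cfd does not stand for adipocyte markers as a set. In B6 11 of 15 macrophage genes were higher too (adjusted p = 0.000922, adjusted p = 0.380 with an estimated correlation). Cell marker lists called in other strains were lost with an estimated correlation: macrophage genes higher in NZO (adjusted p = 0.0428, then 0.693), stellate cell genes higher in WSB (0.000657, then 0.416), hepatocyte genes higher in AJ (0.0368, then 0.317), and blood genes lower in CAST (0.0164, then 0.528) and higher in NOD (0.0379, then 0.520). AJ had less of 15 of 20 male-biased genes and more of 2 (adjusted p = 2.4e-07, adjusted p = 0.317 with an estimated correlation), with Cyp4a12b at -3.85 ± 0.23, and WSB had more of 16 and less of 1 (adjusted p = 1.2e-05, adjusted p = 0.416 with an estimated correlation). Among single genes, CAST was highest in Moxd1 (7.57 ± 0.40) and Ugt1a10 (7.12 ± 0.25) and lowest in Tsnax (-6.73 ± 0.07) and Rarres1 (-6.57 ± 0.29). PWK was lower in the dehydrogenase Sdr9c7 (-7.00 ± 0.17), WSB higher in the collagen Col5a2 (6.22 ± 0.18) and lower in Nxpe2 (-6.39 ± 0.17), and NZO higher in Cyp2c39 (4.26 ± 0.25) and lower in the antiviral Mx2 (-5.84 ± 0.19). NOD was higher in the chemokine Cxcl14 (4.72 ± 0.28) and lower in B4galnt1 (-5.34 ± 0.20), 129S1 higher in Sult1e1 (4.98 ± 0.34) and lower in Ugt2b38 (-5.74 ± 0.26), B6 higher in Gvin1 (4.48 ± 0.58) and lower in the complement protease C1s2 (-4.56 ± 0.28), and AJ higher in the GTPase Gbp11 (3.81 ± 0.26) and in Cyp4a14 (3.38 ± 0.51). Without the wild-derived CAST, PWK and WSB, Cyp4a14 in AJ no longer passed (1.21, adjusted p = 0.0628, over all its alternatives 4.15e-11 to 0.0628). The counts were 8615 genes in CAST, 8019 in PWK, 7388 in WSB, 6283 in AJ, 6258 in NOD, 6177 in 129S1, 6114 in NZO and 5730 in B6. For the 5 classical strains these sum to 30562, and to 24621 when only those strains were compared. How far the counts and single genes of a strain depend on the alignment of its reads was not tested.

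The founder diet effect, averaged over 8 strains, asks which responses to high fat are shared by inbred males. Cholesterol genes fell and lipid droplet genes rose, and the single genes named first are those changed most among assigned symbols with a mean log2 CPM of 1 or more. Sqle was 8.33-fold lower on high fat (log2 change -3.06 ± 0.24 SE; limma adjusted p = 2.36e-20), and Idi1, Cyp51, Nsdhl, Msmo1 and Fdps were 3.75-fold, 3.55-fold, 3.15-fold, 3.13-fold and 3.00-fold lower. The secreted peptide Tff3 was 3.81-fold lower. The pantetheinase Vnn1 (ENSMUSG00000037440) was 3.16-fold higher (1.66 ± 0.16; adjusted p = 7.32e-15), and the droplet protein Fitm1 2.94-fold (1.56 ± 0.10; adjusted p = 9.82e-25). Cyp3a11, a drug-metabolizing enzyme, rose 2.66-fold, and the retinoic acid hydroxylase Cyp26a1 rose by 1.21 ± 0.18. Chrna2 (1.28 ± 0.17), Adam11 (1.28 ± 0.11) and Adgrv1 (1.23 ± 0.17) also rose, as did Cyp4a14, 2.65-fold higher (1.41 ± 0.34; adjusted p = 0.000704). Cyp4a14 rested on NZO, where it rose by 5.43 ± 0.95, and without that strain the change was 0.83 (adjusted p = 0.0750, over all its alternatives 2.67e-06 to 0.0750). All 23 cholesterol genes fell (23 adjusted over the list alone; camera adjusted p = 1.69e-49, adjusted p = 0.00068 with an estimated correlation), including Tm7sf2 (-1.03 ± 0.08). Lipid droplet genes rose in 9 of 14 (11 adjusted over the list alone; adjusted p = 5.2e-08, adjusted p = 0.0127 with an estimated correlation), with Mogat1 at 1.57 ± 0.14 and Cidea at 1.06 ± 0.15. Hepatocyte markers fell slightly in 6 of 8 genes (6 adjusted over the list alone; adjusted p = 0.0013, adjusted p = 0.0358 with an estimated correlation), with Ass1 at -0.33 ± 0.06. Oxidation genes rose in 19 of 24 (20 adjusted over the list alone; adjusted p = 3.41e-16, adjusted p = 0.0613 with an estimated correlation), with Acaa1b at 1.06 ± 0.12, and xenobiotic enzymes rose in 5 of 16 and fell in 2 (8 adjusted over the list alone; adjusted p = 0.000276, adjusted p = 0.152 with an estimated correlation), with Ephx1 at 0.95 ± 0.10. Fatty acid synthesis was not called (adjusted p = 0.622), with 5 genes up and 6 down (13 adjusted over the list alone): Fasn fell (-0.72 ± 0.11) while its regulator Srebf1 rose (0.48 ± 0.11). The adipocyte list, with the single gene Cfd (0.97 ± 0.15) tested, was called at adjusted p = 0.0449 (adjusted p = 0.0613 with an estimated correlation) and not without the pair of males nearest to another strain (adjusted p = 0.0657). Of 13535 genes 3141 (23.2%) changed, 1776 up and 1365 down, and 3291 without that pair.

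The interaction of strain and diet asks which founder strains respond differently. Ly6e (ENSMUSG00000022587), an interferon-inducible surface protein, fell in WSB from 10.27 ± 0.64 to 7.83 ± 0.34 (SD, n = 8 per group) and rose in NZO by 0.74 ± 0.24 SE (limma F 16.5, adjusted p = 1.68e-11). The interferon-induced Ifi27 also fell in WSB (-1.95; F 12.4, adjusted p = 1.07e-08). The imprinted RNA Meg3 rose by 4.23 in PWK, with a wide spread on high fat (7.23 ± 2.23 SD), and fell by 1.62 in B6 (F 15.5, adjusted p = 6.17e-11). The collagen Col5a2 fell in PWK (-3.44) and WSB (-1.60; F 13.03, adjusted p = 3.41e-09). The zinc transporter Slc39a4 rose in CAST (1.00 ± 0.21) and fell in B6 and PWK (-1.08 ± 0.21 each; F 11.5, adjusted p = 4.63e-08), and the steroid hydroxylase Cyp2a4 rose in NZO (4.85 ± 0.66) and fell in AJ (-2.82 ± 0.66; F 10.99, adjusted p = 1.16e-07). Without CAST, PWK and WSB the calls of Ly6e (F 3.44, adjusted p = 0.175), Meg3 (F 4.07, adjusted p = 0.118), Col5a2 (F 0.155, adjusted p = 0.978) and Ifi27 (F 0.428, adjusted p = 0.889) ended. These were the highest over their alternatives, whose lowest adjusted p were 1.07e-11, 5.12e-11, 4.95e-23 and 3.59e-11. In all 1133 of 13535 genes (8.37%) passed, 318 without NZO and 189 without the wild-derived strains. Within strains, the cholesterol list fell in each of the 8, with adjusted p from 1.1e-36 in CAST to 2.5e-10 in PWK. With an estimated correlation it held in CAST (adjusted p = 0.00698), AJ (0.0115), 129S1 (0.0307) and NOD (0.0394), and not in B6 (0.0889), NZO (0.109), WSB (0.320) or PWK (0.40). B6 raised 7 of 14 lipid droplet genes (adjusted p = 1.08e-18, adjusted p = 5.79e-06 with an estimated correlation), with Cidea at 5.39 ± 0.42 and Cd36 at 2.25 ± 0.29. NZO raised 21 of 24 oxidation genes (adjusted p = 5.05e-21, adjusted p = 0.033 with an estimated correlation), among them Acaa1b (2.49 ± 0.35), and 9 female-biased genes (adjusted p = 5.33e-08, adjusted p = 0.033 with an estimated correlation), among them Cyp2b9 (6.14 ± 0.73). WSB lowered 4 of 15 macrophage genes (adjusted p = 7.46e-06, adjusted p = 0.22 with an estimated correlation), with Gpnmb at -2.83 ± 0.63 and Trem2 at -1.90 ± 0.44, and PWK raised 3 acute phase genes (adjusted p = 8.53e-08, adjusted p = 0.40 with an estimated correlation), with Orm1 at 2.15 ± 0.42. The counts of changed genes were 2367 in NZO, 718 in WSB, 427 in B6, 366 in PWK, 195 in 129S1, 184 in NOD, 18 in AJ and, in CAST, 69 up and 89 down. AJ had 938 genes at an unadjusted p under 0.05 and 34 past the adjusted threshold without the pair of males nearest to another strain. That pair is labelled B6 and NOD, and the B6 and NOD values in this paragraph include it. Without it the counts over all strains summed to 4806, against 4433 with it. The cholesterol list then fell in 16 of 23 genes in B6 (camera adjusted p = 1.00e-23) and 17 of 23 in NOD (3.09e-38). Lipid droplet genes then rose in 7 of 14 in B6 (camera adjusted p = 3.28e-16). These values are at the preset correlation, and none with an estimated correlation is given for them.

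**Figure D4:**
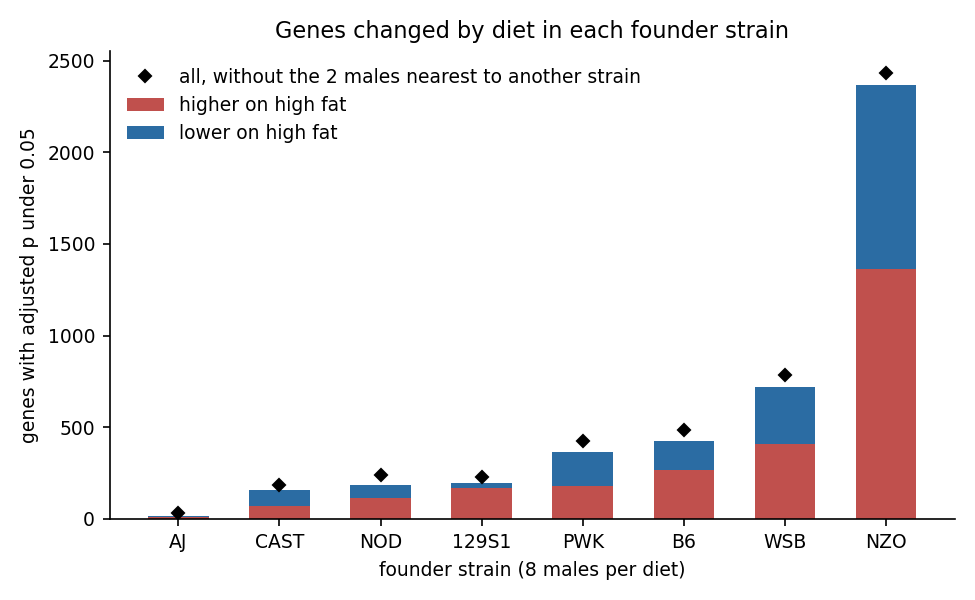
Genes that rose (red) and fell (blue) with high fat in each founder strain, with 8 males per strain and diet, limma adjusted p under 0.05. Black diamonds give the totals without the pair of males nearest to another strain, which is labelled B6 and NOD. AJ and NZO hold no male of that pair, and their totals still moved, to 34 in place of 18 and to 2433 in place of 2367.

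Diet effects in DO males and founder males ask how far the same response appears in mixed and inbred genomes. For 3 cholesterol enzymes no difference was detected: the change in Sqle was -3.03 ± 0.23 SE in DO males and -3.06 ± 0.24 in founders (difference adjusted p = 0.960), that in Cyp51 -1.94 and -1.83 (0.718), and that in Idi1 -2.32 and -1.91 (0.183). Several fat-responsive genes rose more in the DO: Vnn1 by 2.85 against 1.66 (difference 1.19, adjusted p = 0.000296), Apoa4 by 2.57 against 1.03 (difference 1.54, adjusted p = 8.46e-11) and Cd36 by 1.91 against 0.72 (difference 1.19, adjusted p = 2.54e-09). Enho fell further in the DO (-2.56 against -0.86; adjusted p = 6.51e-07). Pnpla3 rose in DO males by 3.11 ± 0.29 and did not pass in founders (-0.06 ± 0.21, adjusted p = 0.882; difference 3.17, adjusted p = 9.00e-16). A pair of cytochromes went opposite ways: Cyp26a1 (ENSMUSG00000024987) fell in DO males (-1.19 ± 0.22) and rose by 1.21 ± 0.18 in founders, and Cyp3a11 fell (-0.38 ± 0.15) and rose by 1.41 ± 0.18 (difference adjusted p = 4.28e-15 and 9.08e-12). Pnpla3, Cyp26a1 and Cyp3a11 were picked for this contrast after their values were seen. Across 13375 genes the effects had Pearson r 0.365 and Spearman rho 0.266, genes not being independent replicates. Both called 833 genes up (463 expected by chance) and 604 down (344 expected), and 369 in opposite directions. Site, diets, storage, alignment and count scale all differ between the populations, so the 4481 genes with different effects do not isolate genetic background.

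The alignment comparison asks how much expression values depend on whether reads are placed on a reference or on each animal's own genome. The 8 largest gains and 8 largest losses among genes with an assigned symbol included desaturase, serpin and carboxylesterase genes and several pseudogenes. Changes are relative to each animal's median gene: without centring the median gene was higher by 0.90 log2 in recovered counts of the individualized table. Relative to it, alignment to individualized genomes raised the class I gene H2-T24 by 1.04 ± 1.48 (SD; higher in 190 of 277 animals), Mup21 by 0.93 ± 0.59 (277 of 277), the desaturase Scd2 by 0.73 ± 0.68 (244), Cyp3a57 by 0.77 ± 1.02 (201), Synb by 0.84 ± 0.82 (211), Nxpe4 by 0.72 ± 1.28 (178), Hist2h2ac by 0.85 ± 0.80 (237) and Rpl21-ps12 by 1.60 ± 2.85. Rpl21-ps12 was higher in a minority of animals (36.5%), with a median ratio of recovered counts of 2. For H2-T24 that median ratio was 2.00 as well, so its mean change does not describe a typical animal. The rank correlation of H2-T24 between the alignments was 0.0145. Relative to the median gene it lowered the serpin Serpina3c (-4.05 ± 4.07; higher in 57 of 277), the desaturase Scd4 (-1.14 ± 1.73; 74), the carboxylesterase Ces1b (-0.98 ± 0.77; 12) and the glycerol channel Aqp7 (-0.97 ± 1.15; 13). In recovered counts without centring the last 3 no longer passed, with mean log2 changes of -0.19 for Scd4, -0.03 for Ces1b and -0.01 for Aqp7 and median ratios over animals of 1.02, 1.11 and 1.28, while Serpina3c stayed lower (-3.10). The ribosomal and translation pseudogenes Eif3s6-ps2 (-4.16 ± 1.26; 1), Rplp0-ps1 (-2.25 ± 2.38; 21) and Rpl13-ps1 (-1.32; 5) were also lower relative to the median gene, the last without passing when uncentred (-0.37), and reads of all these paralogs and pseudogenes are uncertain in origin. Ccdc82 (ENSMUSG00000079084) was lower than the median gene in every animal by nearly the same amount (-0.97 ± 0.02; limma treat adjusted p = 6.22e-250), but its recovered count was nearly the same in both tables (median ratio 0.987; uncentred log2 change -0.02, not passing), with a rank correlation of 0.98 between the alignments. In all 571 of 16391 genes differed by more than 1.2-fold, 65 gains and 506 losses. Scaled to each column total the split was 77 gains and 203 losses of 280, and on recovered counts without centring 16251 gains and 19 losses of 16270. Animals were ranked alike for most genes: the median Spearman rho over animals was 0.954 in 15635 genes, with 3929 (25.1%) below 0.9 and 0.697% below 0.5. Deposited totals were 138935 ± 60400 (SD) under individualized alignment and 53343 ± 21350 under NCBIM37, but the tables were normalized to different upper quartiles by a divisor not given, so these totals do not compare the alignments. Recovered count totals stood at a ratio of 1.90 ± 0.0357 (SD; 1.78 to 1.98).

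**Figure D5:**
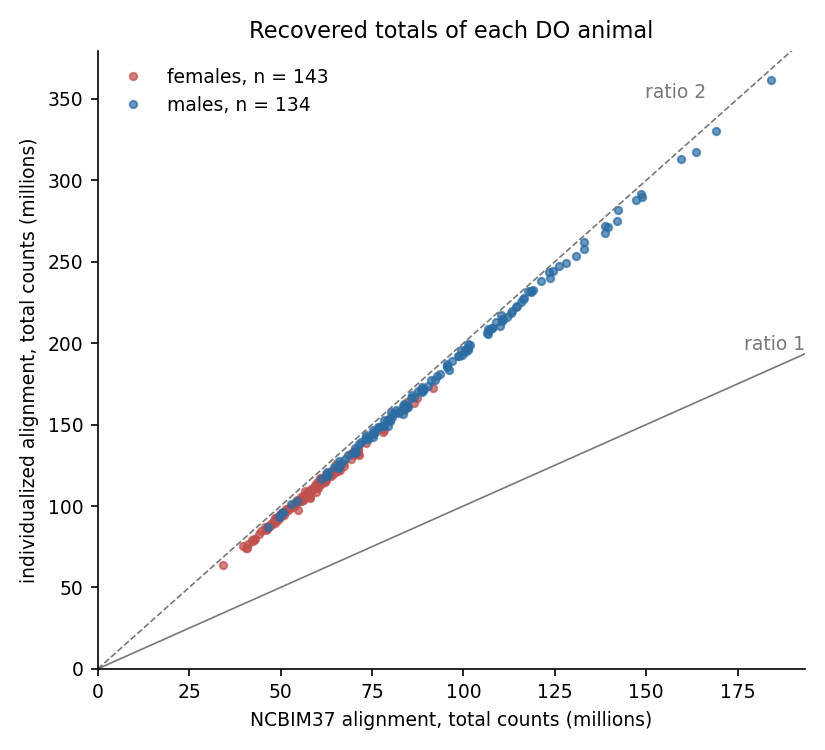
Recovered count totals (M) per DO animal, NCBIM37 alignment on the x axis and individualized alignment on the y axis, females in red and males in blue (277 animals). Lines mark ratios of 1 (solid) and 2 (dashed), and the animals lie between 1.78 and 1.98.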

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

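Of the tests in this part, those of more reads having aligned, of the founders' own levels and of exchanged labels were chosen after the result was seen. The others were set down before.

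Responses to diet that differed between the sexes were picked out because the difference itself passed its test in the DO. On the log2 scale, the change in males less that in females was positive for Rtn4 (0.86) and Ubb (0.47) and negative for Fabp5 (-2.14), Ttc39c (-0.95), Gstp1 (-1.33) and Gstp2 (-1.32). Fabp5 rose in females, whereas Ttc39c, Gstp1 and Gstp2 fell in males. Responses that differed among founder strains were Ly6e (F 16.5, from -2.44 in WSB to 0.74 in NZO), Meg3 (F 15.5, from -1.62 in B6 to 4.23 in PWK), Col5a2 (F 13.03, from -3.44 in PWK to 0.16 in AJ), Ifi27 (F 12.4, from -1.95 in WSB to -0.17 in NOD), Slc39a4 (F 11.5, from -1.08 in PWK to 1.00 in CAST) and Cyp2a4 (F 10.99, from -2.82 in AJ to 4.85 in NZO). Ly6e and Ifi27, both induced by interferon, shared their lowest response in WSB.

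Single samples far from the rest of their group numbered 11 over all founder groups and measures tested, where chance gives about 1 in 20 groups, or 5.6. A CAST high fat animal had 14.1 M counts (rest 7.58 to 9.94) and a NOD control animal 10.4 M (rest 7.86 to 8.92). For Ly6e, 1 animal of 129S1 on high fat stood at 10.50 (rest 9.26 to 9.79) and 1 of CAST on the control diet at 7.87 (rest 8.64 to 9.33). Meg3 was 2.88 in 1 AJ control animal (rest 1.61 to 2.19). Col5a2 was 4.66 in 1 AJ animal on high fat (rest 3.82 to 4.19) and 9.29 in 1 B6 control animal (rest 4.49 to 4.93). Slc39a4 was 8.89 in 1 AJ control animal (rest 7.24 to 7.72) and 7.49 in 1 CAST animal on high fat (rest 8.25 to 8.83). Cyp2a4 was 7.46 in 1 B6 control animal (rest 0 to 2.99) and 3.63 in 1 CAST control animal (rest 7.16 to 9.55). The B6 values of Col5a2 and Cyp2a4 belong to the same animal, B6 control diet replicate 5.

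Totals in the individualized table were close to 2 times those in the NCBIM37 table. More aligned reads as the cause is argued against, since 39.7% of gene and animal values lay within 1% of a ratio of exactly 2. Counting a read 1 time for every haplotype it matches may be the cause: X-linked genes of males, whose single X leaves no difference between haplotypes, were at exactly 2 times more often than those of females in 91.9% of pairs of a male and a female (medians 83.5% and 60.95% of genes). The bound set for it was 95%, so the test leaves it open. Stretches where an animal's haplotypes differ would lower the ratio in neighbouring genes together, and their rank correlation was 0.564, against -0.0004 after shuffling. Whether this raises male values of X-linked genes stays open, at a shift of 0.0286 log2 that lies between the bounds of 0.02 and 0.05.

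For the pair of founder males nearest to each other's strain, RNA of both strains in each library is argued against: at genes far higher in the labelled strain, the median share of the excess left was 0.255% (22 genes) in the library labelled B6 and 1.08% (32 genes) in that labelled NOD. An exchange of the labels of B6 control diet replicate 4 and NOD high fat replicate 3 may be the source, since each had moved at least 93.98% of the distance between the strain means. Hc was 11.47 in the library labelled B6 (other B6 control males 13.20 ± 0.19 SD, n = 7) and 13.36 in the library labelled NOD. The diet-responsive Sqle was 3.77 in the library labelled B6 control diet, where other B6 control males averaged 8.99 ± 1.51 and NOD males on high fat 3.60 ± 0.24, and 9.20 in the library labelled NOD high fat. No biological explanation was tested.

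Abundant genes took a larger share of counts in DO males than in founder males, the Mup genes 39.3% ± 11.9 (SD) against 8.17% ± 3.89. The founders' own levels mixed in the DO are argued against as the whole cause, because the median DO male gave 38.9% of NCBIM37 counts to its 10 most abundant genes and the highest founder 32.6%. Alignments to several isoforms or gene copies counted more than 1 time in the DO tables may contribute: across 11638 genes the ratio of shares rose with annotated transcripts (Spearman rho 0.447, and 0.453 given mean expression). Site, diet and storage stay open as untested.

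Chance is argued against as the source of the counts of changed genes in the group comparisons. In each, only 1 of 100 regroupings, the real one, gave as many. For the founder strains only the counts summed over strains were regrouped, so the count of a single strain was not tested. The real count and the highest of the others were 10520 and 272 for DO sex, 9867 and 2 for diet, 1490 and 2 for their interaction, 7236 and 1 for diet in females, and 8009 and 2 in males. In the founders they were 12886 and 1 for strain, 3141 and 220 for diet, 1133 and 21 for strain by diet, 4433 and 866 for diet in each strain, and 54584 and 541 for each strain against the other 7. For alignment they were 571 and 0. Flipping signs there removes the mean change, so calls beyond 1.2-fold could hardly occur, and this comparison cannot decide about chance.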

How the results depend on the processing

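Some alternatives in this part were chosen after the data were seen. These were a pseudocount of 10 for group comparisons, and edgeR and uncentred values on recovered counts. So were leaving out the 2 females lowest in Xist or the 2 founder males nearest to another strain. Leaving out the 2 animals with differing sex records from the DO and founder comparison was chosen then too. A pseudocount of 1 on the deposited scale is the planned form for a normalized unit, run as an alternative once the main setting departed from it. With it 10528 genes passed for DO sex and 9887 for DO diet. Over all alternatives the log2 sex difference ranged from -9.33 to -3.03 for Sult2a2 and from -9.03 to -4.64 for Xist. Of the alternatives to the counts of genes and other summaries, 29 moved a value by more than 1.5 times and the others did not. The ranges were 2412 to 10657 genes for DO sex, 1129 to 10157 for DO diet, 96 to 2850 for their interaction, 784 to 7659 for diet in females and 907 to 8671 in males. They were 9907 to 16719 for founder strain, where all 9 alternatives stayed within that bound, 189 to 1408 for strain by diet, 586 to 5093 for diet in each strain and 20301 to 63125 for strains against the other 7. Concordance of the alignments ranged from 3111 to 4095 genes below 0.9, and the correlation of DO and founder diet effects from 0.290 to 0.397. Requiring more than 1.2-fold by treat left 2412 genes for sex, 1129 for diet, 96 for their interaction, 784 for diet in females, 907 in males, 1.5e+02 for founder diet, 586 over the strains and 20301 for strains against the other 7, by construction a stricter test. A threshold of 0.01 left 656 for the DO interaction, 1956 for founder diet, 389 for strain by diet and 1905 for diet in each strain. Block 1 alone gave 2850 for the DO interaction and 8671 for diet in males, more than all animals together, and the larger block 2 gave 771 and 3984. Block 1 gave 360 for alignment. The cause of these was not tested. Without NZO, strain by diet fell to 318, with fewer strains, while diet in each strain summed to 2200 over the other 7, which had 2066 with NZO in the model. Without CAST, PWK and WSB strain by diet fell to 189, and strains against the others summed to 24621 over the remaining 5, which had 30562 before. Alignment calls numbered 2037 with a pseudocount of 10, 1040 with means of 1 or more, 1.8e+02 with means of 100 or more, 1.4e+02 beyond 1.5-fold, 21 beyond 2-fold, 280 when scaled to each column total and 16270 on recovered counts without centring, which keeps the ratio of the totals; for the pseudocount, the means and the column totals the cause was not tested. For DO sex, DO diet, their interaction and founder diet together, called lists numbered 41 with the preset correlation and 10 with an estimated one. With fry, which answers another question, they numbered 62. Lists called within a sex or a strain are not in these counts. Where a change has a direction, genes named for sex, diet, their interaction and the founder comparisons kept it under the alternatives run for them, and 7 of their calls were lost under 1 alternative each: Ubb beyond 1.2-fold, Cyp4a14 for founder diet without NZO, and Ly6e, Meg3, Col5a2, Ifi27 and Cyp4a14 in AJ without the wild-derived strains. Genes named from lists were not recomputed under each alternative. Of the 16 genes named for alignment, recomputed for uncentred recovered counts alone, Rpl13-ps1 (-0.37), Scd4 (-0.19), Ces1b (-0.03), Ccdc82 (-0.02) and Aqp7 (-0.01) lost their calls. Not run were count models in the founders, and treat for F-tests, which offer none. The founders had 8.55 M counts per animal, against 76.2 M in the NCBIM37 table of the DO. Some alignments may be counted more than 1 time in the DO tables. These totals are therefore not taken to compare sequencing depth or counting error. No paired analysis was possible because each animal had a single diet and no shared identifier links animals between groups.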

Other observations

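Of the tests in this part, the mean of the X-linked genes with Y partners and the alternative without F11 and F17 were chosen after the result was seen, the score over sex-biased genes and the share of X-linked genes at 2 times were set down once Xist had been seen but before their own values, and the rho given the variance within founder groups was not set down beforehand.

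Genes named here are among the 20 that varied most between DO animals beyond sex, diet and block, of those with an assigned symbol and a mean log2 of 10 or more. The residual SD was 3.41 log2 units for the sulfotransferase Sult3a2, which also differed widely among founder strains (SD of strain means 3.66). Cyp2b9 (2.12, founders 3.53), Sult2a1 (1.89, founders 3.24) and Cyp2c38 (1.78, founders 3.01) followed that pattern. Other variable genes differed less among founder strains than within founder groups: the acute phase protein Saa1 had an SD of 1.99 in the DO, 0.40 between strain means and 1.11 within founder groups. The metallothionein Mt1 had 1.95, 0.59 and 1.06, the heat shock gene Hspa1b 1.62, 0.63 and 1.03, and the clock outputs Dbp 1.74, 0.98 and 1.53 and Usp2 1.68, 0.94 and 1.12.

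Founder strain differences may segregate among the DO animals and set much of this spread. Across 13375 genes, founder strain variance and DO residual variance had a partial Spearman rho of 0.680 given mean expression, and 0.424 when the variance within founder groups was also given. Genes are not independent replicates, and genes that vary easily in any mouse would raise this value too.

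Xist separated the sexes except in DO female high fat replicate 59, which stood at 29.7 count equivalents where females averaged 30012 and males 110 (13.1 to 1639). In that animal the mean of the X-linked genes with Y partners was 12.49 (males 12.59 ± 0.21, females 12.97 ± 0.21, SD), and its score over sex-biased genes was -3.96 (other females -4.88 to 0.92, males -0.06 to 8.27). Of its X-linked genes 80.8% were at exactly 2 times between the alignments (other females 27.2 to 83.7, median 60.95; males 52.1 to 94.5, median 83.5), with 7 other females at or above that share and 51 males at or below it. A male labelled female and a single X chromosome had been set down as explanations for this animal, which was then left out of the patterns weighed. The first is argued against by a score outside the range of males. The second stays open: the bound set against it, a share within the range of females, was wrong, because that range covers much of the range of males. DO female high fat replicate 65 had 3590 for Xist and a score of -0.55. Without both, 10558 genes differed by sex. The animals whose sample letter differs from the genotyped sex had Xist values of their genotyped sex, 71.9 in DO male high fat replicate 1 and 32708 in DO female high fat replicate 48.

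Mup genes took 9.66% ± 7.49 (SD) of counts in DO females, 12.9% on chow and 6.28% on high fat, and 2.38% in AJ and 13.4% in PWK among founder males.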
